A study of Mus musculus with 24 samples.

How the data were processed

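Chromatin was prepared from about 25 mg of cardiac tissue per biopsy, crosslinked and digested enzymatically, and 5 µg went into each H3K9me2 precipitation, per the labels' protocols. Libraries were made from 10 ng of DNA with 12 PCR cycles and read as pairs of 101 bases. The mice were of the C57BL6 strain, and 24 libraries fall into 4 groups of 6, namely H3K9me2 and input of the area at risk and of the remote myocardium, with the mouse number given by the labels. A number stands for the same animal in all 4 groups, so the numbers pair the samples by design. The design text also names a sham procedure; sham hearts were not analysed here.

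The authors deposited 4 tables over the same 53386 regions of build mm10, each with 12 columns of counts, whole numbers per region and library, as the values themselves show. Bowtie2 2.2.2, SICER 1.1 (a caller of broad domains) and edgeR are named, without their roles, per the submitters' processing notes. How regions were called across libraries, which reads were counted and whether duplicates were removed is recorded by no header or label. Each deposited table also holds a log2 fold change and a log2 mean CPM, edgeR's column names per the file headers, and a p-value with its FDR per region. From the values, the deposited log2 fold change is the last 6 columns over the first 6, that is remote over risk or input over H3K9me2, so its sign is opposite to the one used here. At the deposited FDR under 0.05 the authors' tables held 0 regions for H3K9me2 of the area at risk against the remote myocardium, 9207 for the area at risk against input (4162 higher in H3K9me2), 15223 for the remote myocardium against input (7593 higher in H3K9me2) and 0 for the inputs. The fold changes computed here correlated with those of the authors' deposited tables at r = 0.998 to 1.00 across regions with the sign turned, and 8688 and 14558 calls of the input contrasts were shared, none with opposite sign.

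Region widths are multiples of 200 bases, from 200 to 30600 with a median of 2600, and the regions together cover 135.1 Mb, overlaps counted once. Of the regions 77 were listed more than once and 20668 (38.7%) overlap another. The 5113 regions wholly covered by another hold no read in any library, and partly covered regions hold a median of 99.7 reads per kb of full length over the 24 libraries, or 228 per kb of the stretch no other region covers, against 255.8 for regions that stand alone. Reads in overlaps therefore seem to be missing from at least part of the overlapping regions, and counts of partly covered regions understate their full length alike in all libraries. Genes were taken from the RefSeq annotation of GRCm38.p6, the assembly of mm10. The planned class was within 2 kb of a start site, but the annotation gives no strand here, so a region within 2 kb of either end of a gene was called gene end, another region inside a gene gene body, and the rest intergenic. Regions reached 16541 of 34631 annotated genes and 12039 of 21900 protein-coding genes; 38.9% were gene end, 44.8% gene body and 16.4% intergenic. Coordinates are printed as the files give them.

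Total counts per library averaged 739994.5 (SD 296109.5) for H3K9me2 of the area at risk, 707905.5 (SD 178020.3) for H3K9me2 of the remote myocardium, 1687386 (SD 447934.7) for input of the area at risk and 1597897 (SD 140851.6) for input of the remote myocardium. They count reads in the listed regions only, and the sequencing depth outside them is unknown. The median standard error of a log2 fold change was 0.21 between H3K9me2 libraries, 0.20 and 0.19 against input and 0.16 between inputs.

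Each contrast was fitted to its 12 libraries with edgeR 4.0.16 (R 4.3.3), with TMM normalization, the filterByExpr filter on low counts and the two-sided quasi-likelihood test, and called at a Benjamini-Hochberg FDR of 0.05. Every adjusted p of a region is from that test unless another tool is named. The input-corrected difference is the interaction term over all 24 libraries. DESeq2 1.42.0 was run as the other tool on the 4 contrasts of 2 groups. Tests, samples, gene lists, the rule for named genes and the alternatives were written before the data were examined, and the sensitivity part names those added later. Alternatives were the mouse as replicate block, median-of-ratios size factors, no TMM, DESeq2, no filter, each mouse left out, FDR 0.01, a log2 fold change of at least 0.5, regions at or above the median abundance, autosomes only and Bonferroni correction.

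Same-mouse deviations from the group means correlated from -0.20 to 0.05 between the H3K9me2 libraries of the biopsies, from -0.02 to 0.18 between H3K9me2 and input of the area at risk, from 0.00 to 0.09 in the remote myocardium and from -0.09 to 0.04 between inputs. The pairing thus comes from the animals and is faint in the counts. Between libraries of a group, chi-square per region ran from 1.02 to 2.03, so no library is a copy of another library of its own group. Counting noise alone gives a value near 1, so the measure cannot tell whether libraries came from the same material.

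Simulated data used the real dispersions and depths and a mean per region pooled over both groups. For the interaction the means were fitted without that term. In these data 100 regions changed 1.5-fold and 100 changed 2-fold. The fit called 21 and 72 of them among 31526 regions for H3K9me2 between biopsies, 17 and 76 among 40928 for the area at risk against input, 27 and 81 among 40767 for the remote myocardium against input, 53 and 85 among 42603 for the inputs, and 3 and 36 among 42445 for the interaction. In the contrast of H3K9me2 between biopsies 94 and 79 of the changed regions passed the filter on low counts, and in the interaction all 100 each. Of unchanged regions 2 to 6 were called per simulation. The biological coefficient of variation was 9.50%, 11.6%, 5.15%, 8.73% and 9.05% in the same order. In the real contrasts against input 23.6% and 40.5% of tested regions were called, far more than were changed in the simulation. The FDR cut is stricter where few regions change, so the simulated counts do not give the power of those 2 contrasts.

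Named regions followed a fixed rule. Among regions past FDR 0.05 with abundance at or above the median and the same direction in at least 5 of 6 mice, the 10 of largest change per direction were taken. Where fewer than 5 passed, the 5 of smallest p per direction were taken as values that did not pass. Mtor and Ehmt2 were always taken, and the 3 members of smallest p of each list with at least 5 measured genes. A gene with several regions stands by its region of smallest p. The text gives part of these in full.

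Of 19 lists 17 had at least 5 genes with a tested region. Leukocyte and blood genes (3 genes) and vomeronasal receptors (2 genes) had too few and were not tested. Symbols matched to regions for 19 of 22 mTOR genes, 24 of 30 autophagy genes, 25 of 29 immediate early genes and 15 of 1428 odorant receptor genes, so the receptors seen are a small part of the family. Each list's median log2 fold change was set against 10000 random lists of the same size matched in 20 abundance bins, two-sided, with adjustment over lists. camera (preset correlation 0.01, and estimated) and fry from limma 3.58.1 were run beside it. fry, which tests whether the genes of a list move on balance in a direction without setting them against other genes, passed 15 lists in the area at risk against input, 14 in the remote myocardium and 0 in the other contrasts. Position classes were compared with Fisher's exact test.

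Enrichment strength used 29892 regions that overlap no other and average at least 15 reads per library. It is the slope of a library's log2 ratio over its own input (2 reads added to each count) on the mean log2 ratio of the 10 H3K9me2 libraries of the other mice. Means of strength and of chromosome X shares were tested with exact sign-flip tests over 64 sign patterns. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps. No genome sequence was used, so GC content was not checked.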

Results

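The series measured dimethylation of histone H3 at lysine 9 (H3K9me2), a mark of silenced chromatin written mainly by the methyltransferases encoded by Ehmt2 (G9a) and Ehmt1, in hearts of 6 mice after ischemic preconditioning. Preconditioning exposes the heart to brief cycles of coronary occlusion and reperfusion, here 4 cycles of 5 min each followed by 30 min of reperfusion. From each heart the area at risk, which lost its blood supply during occlusion, and the remote myocardium, which did not, were sampled. Chromatin immunoprecipitation with sequencing (ChIP-seq) for H3K9me2 and a matching input library were made from each biopsy, giving 4 groups of 6 libraries from 3 female and 3 male mice aged 12 months. No sham-operated heart is among the samples, so the contrasts compare tissue within preconditioned hearts. Counts covered 53386 genomic regions of build mm10. Total counts per H3K9me2 library ran from 416683 to 1196368 in the area at risk and from 443261 to 981763 in the remote myocardium. Inputs ran from 1286383 to 2478668 and from 1405503 to 1770520. Positive log2 fold changes below mean higher in the area at risk, or higher in H3K9me2 than in input.

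The contrast of H3K9me2 between area at risk and remote myocardium asks whether the tissue that went through the occlusions distributes the mark differently over the listed regions. Libraries were scaled to their totals in these regions, so a rise or fall alike in all regions could not be seen. No region passed. edgeR called 0 of 31526 tested regions at FDR 0.05, with 1272 at an unadjusted p under 0.05 and a smallest adjusted p of 0.735. DESeq2 also called 0, with 454 at an unadjusted p under 0.05. The regions of smallest p that lay higher in the area at risk were in Cd276 (an immune checkpoint ligand of the B7 family), Camta2 (a transcriptional coactivator in cardiomyocytes), Col15a1 (a basement membrane collagen), Elk3 (an ETS repressor of angiogenesis) and Thoc5 (a subunit of the mRNA export complex). The Cd276 region, at chromosome 9 from 58548800 to 58553599, held 34.7 ± 6.1 CPM (counts scaled to the library total) in the area at risk and 18.0 ± 5.86 in the remote myocardium (SD, n = 6). Its log2 fold change of 0.89 (SE 0.20) was seen in 6 of 6 mice, with an edgeR adjusted p of 0.735. The Camta2 region, at chromosome 11 from 70668600 to 70677199, had a log2 fold change of 0.81 (SE 0.19) in 5 of 6 mice and an edgeR adjusted p of 0.735. Without mouse 19 the Camta2 region was the 1 region called, at a log2 fold change of 1.01 and an adjusted p of 0.0179. On the lower side the smallest p belonged to regions in Nfia (a nuclear factor I transcription factor, log2 fold change -0.92), Sdk1 (a cell adhesion molecule, -0.74) and an intergenic stretch of chromosome 4 from 154705600 to 154709799 (-0.55). The noncoding gene 4930488B22Rik (-0.65) and the flank of Pabpc1l (a poly(A)-binding protein, -0.68) came next, and none of these passed. In the authors' deposited table of this contrast 0 regions had an FDR under 0.05, the smallest being 0.292, and 1642 had a p under 0.05.

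Neither Mtor nor Ehmt2, the gene of the main H3K9me2 writer, had a region that passed between the biopsies. Mtor, the kinase at the centre of both mTOR complexes and a brake on autophagy, had 7 tested regions, 2 above 0 and 5 below. Their log2 fold changes ran from -0.19 to 0.16 with a smallest unadjusted edgeR p of 0.348 in a fit of 6 against 6 libraries, not an exact test. Its region of smallest p, at chromosome 4 from 148507600 to 148510799, held 27.6 ± 7.12 CPM in the area at risk and 31.5 ± 5.15 in the remote myocardium (SD, n = 6). Ehmt2 had 2 tested regions, at log2 fold changes of -0.08 and 0.27. The median over 16 measured genes of the mTOR complex and its regulators was 0.11, at the 77.6th percentile of random lists of like abundance. Rptor, the scaffold of mTOR complex 1, lay at -0.40 and Lamtor1, a lysosomal anchor of that complex, at 0.43, neither passing.

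Of the 17 gene lists tested in this contrast none stood apart from random lists at an adjusted p under 0.05, and in each list 0 regions passed whether adjusted over all regions or adjusted over the list alone. The H3K9 methyltransferases and demethylases had a median of 0.28 over 10 genes (adjusted p = 0.291 by random lists), with Kdm4a, an H3K9 and H3K36 demethylase, at 0.53 and Prdm2, a methyltransferase, at -0.38. The 15 odorant receptor genes, silent outside the nose, had a median of -0.18 (adjusted p = 0.291), with Olfr1330 at -0.56 and Olfr1410 at -0.37. That list passed in the same direction when random lists were also matched on gene length (adjusted p = 0.017) and when a gene was taken as the mean of its regions (adjusted p = 0.0068). camera gave an adjusted p of 0.065, or adjusted p = 0.721 with an estimated correlation. Markers of other cell types did not part the biopsies: fibroblast genes had a median of -0.17 (adjusted p = 0.637) and endothelial and mural genes 0.12 (adjusted p = 0.780). Pdgfra, a fibroblast receptor, lay at -0.43 and Flt1, an endothelial VEGF receptor, at 0.59. Cardiomyocyte sarcomere and calcium handling genes had a median of 0.15 (adjusted p = 0.657), with Casq2, the calcium store of the sarcoplasmic reticulum, at -0.51 and Tpm1, a thin filament protein, at 0.57. Medians of the remaining lists were 0.16 for autophagy machinery, 0.05 for oxidative phosphorylation and fatty acid oxidation, -0.01 for immediate early and stress response genes, 0.11 for the hypoxia response and -0.03 for preconditioning signalling and cell death. They were 0.01 for neuronal genes, 0.09 for germ line genes, 0.11 for housekeeping genes, 0.02 for Hox genes, 0.05 for zinc finger genes and -0.12 for the protocadherin cluster. In that cluster 3 shared regions stood for its 21 genes.

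Within the area at risk, H3K9me2 against input shows which listed regions held a larger or smaller share of the counts than in the input chromatin. Libraries were scaled to their totals in these regions, so the median log2 fold change lay near 0 (0.0115). Lower, depleted and enriched, here and below, are relative to the other listed regions and do not mean absence or presence of the mark. Of 40928 tested regions, 4637 were higher in H3K9me2 and 5033 lower by edgeR at FDR 0.05, or 23.6% of those tested. Among regions at or above the median abundance, depletion was deepest at Midn. A region of this gene, which encodes midnolin, at chromosome 10 from 80156200 to 80161999, held 10.1 ± 5.92 CPM in H3K9me2 and 56.2 ± 6.68 in input (SD, n = 6). Its log2 fold change was -2.25 (SE 0.19) in 6 of 6 mice with an edgeR adjusted p of 1.4e-12. Gnb2 (a G protein beta subunit, log2 fold change -2.08), Zfp36 (an mRNA decay factor induced by stress, -2.04), Cic (a transcriptional repressor, -1.88), Actg1 (cytoplasmic actin, -1.87), Kdm6b (an H3K27 demethylase, -1.85), Nfic (a nuclear factor I protein, -1.83) and Rhof (a small GTPase, -1.82) followed. Enrichment was shallower and lay in intergenic stretches and in scattered genes. The intergenic region at chromosome 14 from 68884600 to 68886999 rose to 38.8 ± 14.6 CPM from 16.1 ± 6.34 in input (SD, n = 6), a log2 fold change of 1.20. Regions of Pkd1l2 (a polycystin-1 relative, 1.17), Erlec1 (an endoplasmic reticulum lectin, 1.12), Chil4 (a chitinase-like protein, 1.08) and Galnt17 (a glycosyltransferase, 1.06) were close behind. The median log2 fold change was 0.61 among higher and -0.75 among lower regions.

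Immediate early, housekeeping and mTOR genes were depleted of H3K9me2 as groups in the area at risk. List medians here and below take the region of smallest p in each gene; those of random lists also lay below 0, from -0.26 to -0.05 here and from -0.30 to -0.06 in the remote myocardium. Among 25 measured immediate early and stress response genes, 16 had only lower regions, 9 had none called and 0 had a higher region. The list had a median of -0.89 (adjusted p = 0.0034 against random lists of like abundance). Zfp36, Nr4a3 (an orphan nuclear receptor, -1.45) and Jund (an AP-1 subunit, -1.87) led the list, and 20 of its 38 regions were lower, 22 when adjusted over the list alone. Housekeeping genes had a median of -1.11 (adjusted p = 0.0034) and 12 of 13 genes lower. Gapdh lay at -1.71, Rpl13a at -1.41 and Actb at -1.18, with 16 of 22 regions lower, 19 when adjusted over the list alone. The mTOR complex and its regulators had a median of -0.69 (adjusted p = 0.0363), with 10 of 19 genes lower, 2 higher, 1 both ways and 6 not called. Ddit4, a stress-induced inhibitor of mTOR complex 1, lay at -0.92, Tsc2, part of the complex that holds Rheb inactive, at -0.81 and Akt1, a kinase upstream of mTOR, at -1.07. Of this list's 99 regions 21 were lower and 6 higher, or 22 and 7 adjusted over the list alone, and the median over all of them was -0.15. Its camera call held with an estimated correlation (adjusted p = 0.0479) but not with the mouse as replicate block added (adjusted p = 0.099 with an estimated correlation), and members at or above the median abundance did not pass the random-list test (adjusted p = 0.261).

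For Mtor itself, 10 of 11 tested regions in the area at risk lay below input and none was called. Its region of smallest p, at chromosome 4 from 148448600 to 148451199 at an end of the gene, held 15.9 ± 5.41 CPM in H3K9me2 and 24.2 ± 4.93 in input (SD, n = 6). Its log2 fold change was -0.53 with an edgeR adjusted p of 0.0523. It passed with the mouse as replicate block (adjusted p = 0.0313). Both tested regions of Ehmt2 were lower than input, the one at chromosome 17 from 34906400 to 34908999 at -0.73 with an edgeR adjusted p of 0.00426.

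The other lists of the area at risk fell on both sides of 0. Oxidative phosphorylation and fatty acid oxidation genes had 14 of 22 genes lower and none higher (median -0.60, adjusted p = 0.0646 by random lists). Atp5b, a catalytic subunit of ATP synthase, lay at -1.66 and Cox4i1, a cytochrome c oxidase subunit, at -0.50. H3K9 methyltransferases and demethylases had 7 of 11 lower (median -0.73, adjusted p = 0.0646), with Kdm4b at -0.81, Kdm7a at -1.38 and Jmjd1c at -1.27. Hypoxia response genes had 9 of 17 lower and 1 higher (median -0.56, adjusted p = 0.114). Vegfa, the main angiogenic growth factor, lay at -1.05 and Epas1, a hypoxia-inducible factor, at -1.14. Preconditioning signalling and cell death genes had 14 of 25 lower, 1 higher and 2 both ways (median -0.54, adjusted p = 0.0816). Bad, a pro-apoptotic protein, lay at -0.96 and Gsk3b, a kinase inhibited during preconditioning, at -1.76. Autophagy machinery had 10 of 24 lower (median -0.42, adjusted p = 0.253), with Map1lc3b at -0.73 and Ulk1, the initiating kinase, at -1.03. Endothelial and mural markers had 4 of 13 lower, 2 higher and 2 both ways (median -0.61, adjusted p = 0.0816), and 7 of 21 Hox genes were lower (median -0.44, adjusted p = 0.222). Cardiomyocyte genes split, with 5 of 22 lower, 3 higher and 1 both ways. Their median of -0.38, from the region of smallest p in each gene, was near that of random lists (-0.25, adjusted p = 0.537), and over all 74 regions the median was 0.03, with 10 higher and 9 lower. Atp2a2, the calcium pump of the sarcoplasmic reticulum, lay at -1.65 and Cacna1c, the L-type calcium channel, at 0.67. Zinc finger genes had 50 of 164 lower and 17 higher (median -0.23, adjusted p = 0.877). Of the classes silent in heart, 3 of 7 germ line genes were higher (median 0.42, adjusted p = 0.121), with the RNA helicase Ddx4 at 0.62 and the piRNA factor Piwil2 at 0.69. So were 3 of 15 odorant receptor genes (median 0.31, adjusted p = 0.114), with Olfr691 at 0.97.

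Fibroblast markers of the area at risk had 2 of 8 genes higher and 1 lower (median 0.34, adjusted p = 0.114), Ddr2, a collagen receptor, at 0.69 and Pdgfra at -0.98. Neuronal genes had 1 of 6 higher, 1 lower and 1 both ways, Rbfox3 at 0.73 and Grin1 at -0.58. Their median was 0.00 (adjusted p = 0.718), but -0.50 with the replicate block (adjusted p = 0.359) and 0.18 over all 54 regions, of which 10 were higher and 2 lower. No region of the protocadherin cluster passed (median -0.36 over the 2 regions that stand for its 21 genes, adjusted p = 0.537). By camera 9 lists passed, and 7 of them with an estimated correlation. Hox genes and odorant receptors were lost (adjusted p = 0.158 and adjusted p = 0.204 with an estimated correlation). With the replicate block added, 3 held with an estimated correlation, namely oxidative phosphorylation, immediate early and housekeeping genes. The adjusted p rose to 0.0584 for autophagy and for the H3K9 enzymes and to 0.0874 for the hypoxia response.

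In the remote myocardium, 8360 of 40767 tested regions were higher in H3K9me2 than in input and 8149 lower by edgeR at FDR 0.05, or 40.5% of those tested. Midn was again among the most depleted genes. Its region at chromosome 10 from 80146200 to 80152599 held 9.7 ± 4.63 CPM in H3K9me2 and 64 ± 6.84 in input (SD, n = 6). The log2 fold change was -2.65 (SE 0.18) in 6 of 6 mice with an edgeR adjusted p of 7.19e-33. H2-DMa (a class II antigen loading chain, -2.58), Ubtf (a ribosomal DNA transcription factor, -2.18), Jund (-2.14), Nfe2l1 (a stress-responsive transcription factor, -2.08), Atp5d (an ATP synthase subunit, -2.06), Hnrnpa0 (an RNA-binding protein, -1.99) and Bahcc1 (a chromatin reader, -1.92) followed. On the higher side stood Htr4, a serotonin receptor, at chromosome 18 from 62475600 to 62477999, with 46.0 ± 10.4 CPM in H3K9me2 and 18.3 ± 3.1 in input (SD, n = 6). Its log2 fold change was 1.3 in 6 of 6 mice, with an edgeR adjusted p of 9.23e-13. Mier2 (a transcriptional regulator that recruits deacetylases, 1.29), Dnhd1 (a dynein heavy chain domain protein, 1.24), Fyb2 (a T cell adaptor, 1.22) and Prmt8 (a neuronal arginine methyltransferase, 1.21) were also higher. The median log2 fold change was 0.62 among higher and -0.72 among lower regions.

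Odorant receptor genes carried more H3K9me2 than input in the remote myocardium as a group, with 10 of 15 genes higher and none lower and a median of 0.67 (adjusted p = 0.00113 against random lists). Olfr1410 lay at 0.85, Olfr1415 at 0.90 and Olfr12 at 0.85, and the count of 10 of 16 regions was the same adjusted over the list alone. Germ line genes followed with 5 of 7 genes higher and none lower (median 0.54, adjusted p = 0.0792), among them the sperm chromatin protein gene Prm1 at 0.73 and Ddx4 at 0.66. The opposite held for immediate early and stress response genes, 21 of 25 lower and none higher (median -0.97, adjusted p = 0.00113), led by Jund, Dusp1 (a MAP kinase phosphatase, -2.08) and Zfp36 (-1.90). Housekeeping genes had 12 of 13 genes lower (median -1.24, adjusted p = 0.00113), with Rps18 at -1.36 and Gapdh at -1.77. All 28 lower regions of the immediate early list and 18 of the housekeeping list remained when adjusted over the list alone.

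In the random-list test the mTOR, autophagy and preconditioning lists also passed in the remote myocardium, on the lower side and with calls that depended on the method. The mTOR list had 13 of 19 genes lower, 2 higher and 2 both ways (median -0.72, adjusted p = 0.0468), with Ddit4 at -1.18, Tsc2 at -1.01 and Akt1 at -1.09. Its 35 lower and 10 higher regions of 100 were the same adjusted over the list alone. Autophagy machinery had 15 of 24 lower and 1 higher (median -0.66, adjusted p = 0.0499). Ulk1 lay at -1.32, Map1lc3b at -0.91 and Tfeb, the transcription factor of lysosomal genes, at -1.31. Of its 68 regions 24 were lower, and 24 adjusted over the list alone. Preconditioning signalling and cell death had 15 of 25 lower, 3 higher and 2 both ways (median -0.66, adjusted p = 0.0499), and did not pass camera (adjusted p = 0.0914, and adjusted p = 0.150 with an estimated correlation). Bad lay at -1.14, Bcl2l1, an anti-apoptotic protein, at -1.90 and Prkce, protein kinase C epsilon, at -1.01. Of its 125 regions 36 were lower and 17 higher, the same adjusted over the list alone. With the mouse as replicate block these 3 lists no longer passed the random-list test (adjusted p = 0.0626, 0.0626 and 0.0737), nor among members at or above the median abundance (0.204, 0.130 and 0.176), where odorant receptors were lost too (0.0615). With a gene as the mean of all its regions, autophagy lay at -0.38 (adjusted p = 0.101) and preconditioning at -0.23 (adjusted p = 0.413), so neither passed. Over all regions the medians of the 3 lists were -0.17, -0.26 and -0.10. Of the 11 tested Mtor regions 4 were lower and none higher. The region at chromosome 4 from 148448600 to 148451199 held 13.7 ± 4.54 CPM in H3K9me2 and 22.1 ± 3.34 in input (SD, n = 6). Its log2 fold change was -0.69 with an edgeR adjusted p of 0.00495. Both Ehmt2 regions were lower, at -0.74 and -0.57.

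Of the remaining lists of the remote myocardium, H3K9 methyltransferases and demethylases had 9 of 11 genes lower (median -0.74, adjusted p = 0.0943), with Jmjd1c at -1.70 and Kdm4b at -0.86. Oxidative phosphorylation genes had 12 of 22 lower (median -0.54, adjusted p = 0.188), with Atp5b at -1.48 and Cox4i1 at -0.90. Hypoxia response genes had 10 of 17 lower, 2 higher and 1 both ways (median -0.57, adjusted p = 0.131), with Aldoa, a glycolytic aldolase, at -1.54. Endothelial and mural markers had 7 of 13 lower, 1 higher and 2 both ways (median -0.68, adjusted p = 0.119), with Flt1 at -1.75 and Egfl7, a secreted vascular factor, at -1.50. Hox genes had 12 of 21 lower (median -0.39, adjusted p = 0.481), with Hoxa13 at -1.06 and Hoxa9 at -0.95. Cardiomyocyte genes had 10 of 22 lower, 4 higher and 1 both ways (median -0.31 against -0.22 in random lists, adjusted p = 0.718). Over all 76 regions their median was 0.10, with 16 higher and 21 lower. Tcap, a Z-disc protein, lay at -0.90 and Cacna1c at 0.82. Zinc finger genes had 62 of 164 lower, 29 higher and 5 both ways (median -0.27, adjusted p = 0.718). Zfp978, in a zinc finger gene cluster of chromosome 4, was higher at 426 ± 67.2 CPM against 266 ± 38.7 in input (SD, n = 6). Zfp36l1, an mRNA decay factor that shares only the name pattern, was lower at -1.69. Fibroblast markers had 4 of 8 higher and 3 lower (median 0.32, adjusted p = 0.235), Ddr2 at 1.34 and Vim at -1.18. Neuronal genes had 2 of 6 higher, 3 lower and 1 both ways (median 0.14, adjusted p = 0.419), Stmn2 at 1.06 and Grin1 at -0.79. In the protocadherin cluster, whose genes share regions, 1 of 8 regions was lower, at -0.50 (list median -0.44 over the 2 regions that stand for its 21 genes, adjusted p = 0.481). It did not pass by DESeq2 (log2 fold change -0.49, adjusted p = 0.0521), nor without mouse 17, 23 or 30, with adjusted p of 0.0662, 0.0559 and 0.0647. By camera 10 lists passed, each also with an estimated correlation. With the replicate block added, endothelial and mural markers were lost (adjusted p = 0.0643 with an estimated correlation).

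**Figure D1:**
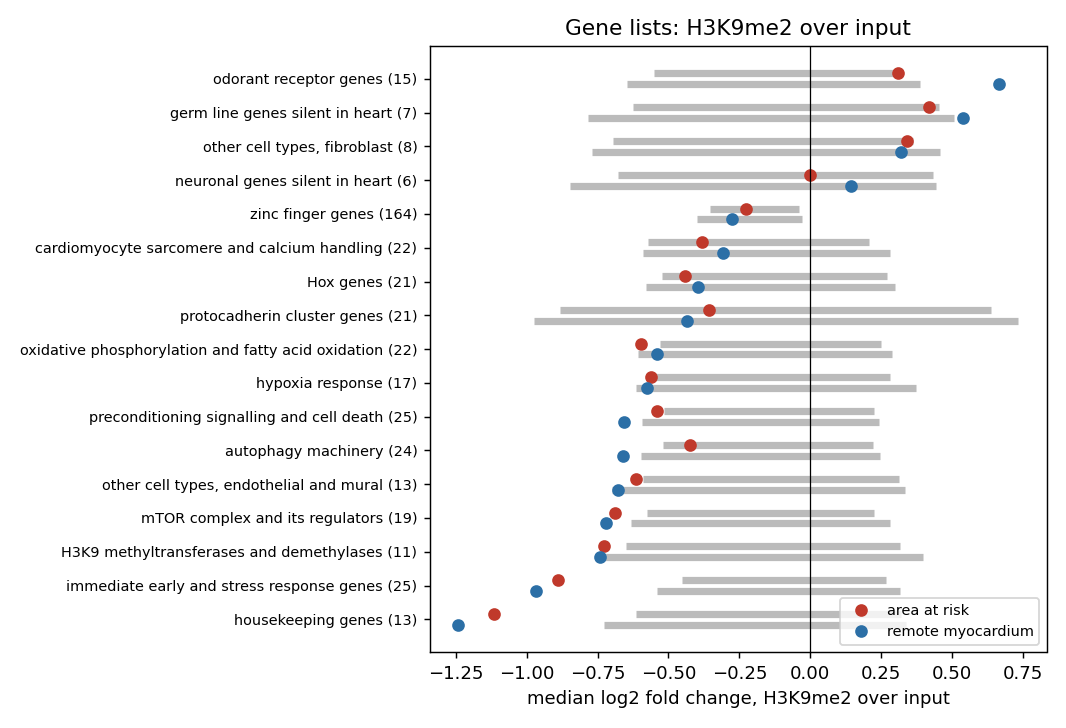
Median log2 fold change of H3K9me2 over input (horizontal axis) for each gene list (rows, measured genes in the remote myocardium in parentheses), in the area at risk (red) and the remote myocardium (blue). For the protocadherin cluster 2 regions stand for its 21 genes. Grey bars span the central 95% of medians of 10000 random gene lists of like abundance; housekeeping genes lie lowest, at -1.11 and -1.24, and odorant receptor genes of the remote myocardium highest, at 0.67.

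H3K9me2 was depleted at gene ends and enriched in intergenic sequence in both biopsies. In the area at risk 22.7% of 15354 regions within 2 kb of a gene end were lower than input, against 6.05% of other regions (odds ratio 4.56). In the remote myocardium they were 33.3% of 15307 against 12.0% (odds ratio 3.68). Intergenic regions were higher than input in 24.6% of 6920 cases in the area at risk, against 8.62% elsewhere (odds ratio 3.47). In the remote myocardium they were higher in 41.2% of 6909 cases, against 16.3% (odds ratio 3.60). Gene bodies were lower less often than other regions, 7.17% against 16.6% in the area at risk and 14.4% against 24.7% in the remote myocardium (odds ratios 0.388 and 0.512). They were not separated from other regions by the share that was higher (odds ratios 0.944 and 1.01, Fisher's exact test, two-sided, adjusted p = 0.0792 and 0.758). For that last share the direction turned to an odds ratio of 1.13 in the area at risk with a flank of 5 kb and to 0.953 in the remote myocardium at FDR 0.01. On chromosome X, 39 of 66 tested regions were higher in the remote myocardium (odds ratio 5.62, Fisher's exact test, adjusted p = 1.22e-11) and 1 was lower (odds ratio 0.0615, adjusted p = 2.09e-05). In the area at risk 9 of 67 were higher (odds ratio 1.21, adjusted p = 0.599) and 2 lower (odds ratio 0.219, adjusted p = 0.0178). The median log2 fold change of these regions was 0.61 in the remote myocardium and 0.37 in the area at risk. The shares of the biopsies were not tested against each other. Neighbouring regions are not independent, so these odds describe the libraries.

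**Figure D2:**
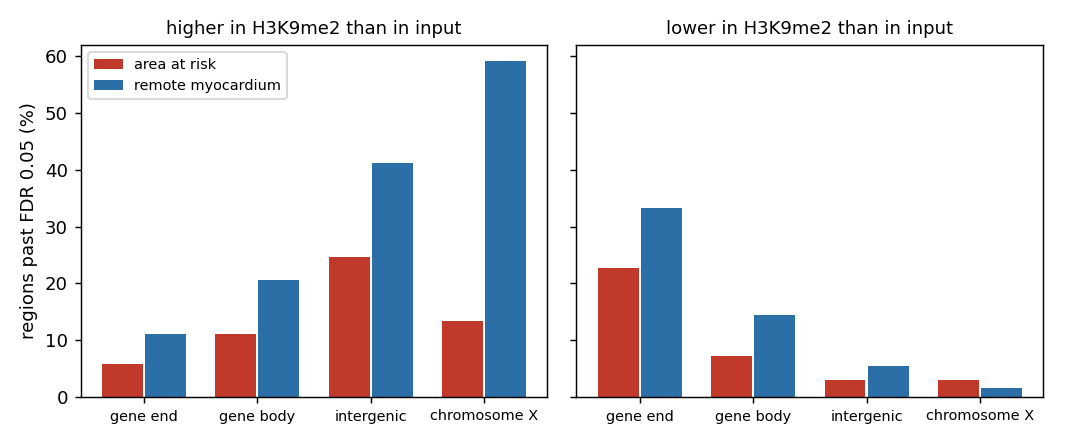
Share of tested regions past FDR 0.05 (vertical axis, percent) that were higher (left) or lower (right) in H3K9me2 than in input, by position class, in the area at risk (red) and the remote myocardium (blue). Higher regions are most frequent in intergenic sequence and, in the remote myocardium, on chromosome X (59.1%), and lower regions at gene ends (22.7% and 33.3%).

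Most regions called in the area at risk were also called in the remote myocardium. In the main fits about as many remote calls were shared as not, and fewer when most single mice were left out. Among 40333 regions tested in both, 3785 were higher than input in both and 4206 lower in both, where independent lists would share 953 and 993. In opposite directions 2 regions were called, where independent lists would give 1948. Of the regions called higher in the area at risk 82.0% were also higher in the remote myocardium, and of those lower 84.7% were also lower; without mouse 23 these shares were 70.4% and 75.1%. In the other direction, 45.5% of 8321 regions called higher in the remote myocardium and 52.1% of 8066 called lower were also called in the area at risk. Without mouse 23 these remote shares were 47.8% and 54.0%, and without any other mouse 31.5% to 38.9% and 44.8% to 47.9%. Across the 40333 regions, which are not independent replicates, log2 fold changes of the biopsies correlated at r = 0.845. Jund, Zfp36, Gapdh, Ddit4 and Flt1 on the lower side, and Ddx4, Piwil2 and Olfr1415 on the higher side, were called in both. The H3K9me2 and input libraries of the biopsies are separate, so no control library is shared. The mice, the listed regions and the protocol are the same, however. The counts for independent lists do not allow for effects of sequence or digestion common to both biopsies, which were not tested.

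The inputs of the biopsies, which carry copy number, mappability and chromatin fragmentation without the antibody, were compared as the background of the first contrast. No region passed. edgeR called 0 of 42603 at FDR 0.05, with 1157 at an unadjusted p under 0.05, and DESeq2 0, with 626. The smallest p on the lower side were in Rnf8 (a DNA damage ubiquitin ligase, log2 fold change -0.59), Ip6k1 (an inositol phosphate kinase, -0.40), Slit1 (an axon guidance ligand, -0.42), Id2 (an inhibitor of helix-loop-helix factors, -0.43) and Taok3 (a kinase, -0.52). On the higher side lay regions of Kctd5 (a ubiquitin ligase adaptor, 0.80), Kcnmb4 (a potassium channel subunit, 0.66) and Eya2 (a developmental phosphatase, 0.68) and 2 intergenic regions. Mtor had 13 tested regions with log2 fold changes from -0.18 to 0.38 and Ehmt2 2 regions at 0.07 and 0.10, none passing, and none of 17 lists stood apart. Without mouse 23 the number of regions at an unadjusted edgeR p under 0.05 rose from 1157 to 2567, with a smallest adjusted p of 0.810.

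Whether the difference between biopsies survives correction for input was tested as an interaction over all 24 libraries. It gave 0 of 42445 regions at FDR 0.05 by edgeR, with 1728 at an unadjusted p under 0.05 and a smallest adjusted p of 0.610. None of the regions called in a single biopsy was shown to differ between biopsies. DESeq2 was not run for this term. The precision limits this. In data simulated with the real depths, 36 of 100 regions changed 2-fold were called by the interaction, where all 100 were tested. The direct contrast of H3K9me2 libraries called 72 of 100, or 91.1% of the 79 that passed its filter on low counts.

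The strength of enrichment per library was measured as the slope of its profile over input on the mean profile of the other mice. It averaged 0.840 ± 0.134 in the area at risk and 0.969 ± 0.104 in the remote myocardium (SD, n = 6), and was lower in the area at risk in 4 of 6 mice. Both means lay below 1, so a value under 1 does not by itself mark a library as weaker than the others. The mean difference of -0.129 (SD 0.197, n = 6) was within the spread between mice (exact sign-flip test, two-sided, p = 0.1875, smallest possible 0.03125). Mouse 23 held the lowest value of the area at risk, 0.685, and the highest of the remote myocardium, 1.16. Without it the difference was -0.06 (exact sign-flip test, n = 5, p = 0.375, smallest possible 0.0625). Over the mean input of the other mice the difference was -0.118, and without mouse 23 it turned to 0.0178 (exact sign-flip test, p = 0.531 and 1). The share of reads on chromosome X was 1.32 ± 0.159 times that of input in the area at risk and 1.46 ± 0.172 times in the remote myocardium (SD, n = 6). It was higher in 6 of 6 mice each (exact sign-flip test, two-sided, p = 0.03125 each, the smallest possible).

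**Figure D3:**
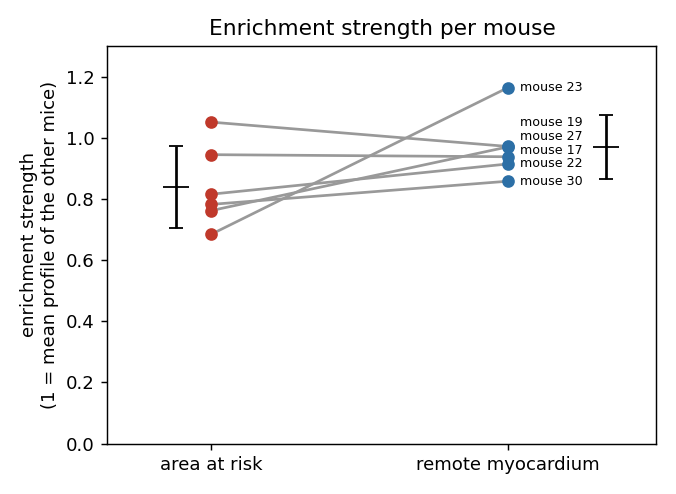
Enrichment strength of each H3K9me2 library in the area at risk and the remote myocardium (vertical axis, no unit). It is the slope on the mean profile of the other mice, and both group means lay below 1. A line joins the values of each mouse, and mean ± SD stands beside each group (n = 6). Mouse labels are spread apart where points overlap. Mouse 23 has the lowest value in the area at risk, 0.685, and the highest in the remote myocardium, 1.16.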

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

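A set of 4 quantities stood far from the rest of their group of 6 libraries, among 42 such groups tested, where chance flags about 1 in 20 groups, or 2.1 here. Of the tests below, those on leaving out a single library, on the difference in strength between biopsies, on a label swap and on the relation of strength to library total were chosen only after the result was seen; thinning, the kept shares and the other splits were written before.

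The enrichment strength of the remote H3K9me2 library of mouse 23 was 1.16, with the next highest remote library at 0.971. In the Cd276 region the remote library of mouse 22 held 6.77 CPM, with the nearest other at 17.5. In the Nfia region the remote library of mouse 22 held 40.6 CPM, with the nearest at 23.4. In the Sdk1 region the area-at-risk library of mouse 22 held 45.6 CPM, with the nearest at 20.1. Mouse 22 has the fewest H3K9me2 counts in both biopsies, 416683 and 443261. The 104 regions named for H3K9me2 against input were also checked for opposite directions. None moved one way in every mouse of a biopsy and the opposite way in every mouse of the other. They were chosen by size of change or smallest p, so this does not speak for other regions.

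Fewer regions differed from input in the area at risk (9670) than in the remote myocardium (16509). The weakly enriched area-at-risk H3K9me2 library of mouse 23 carries part of the gap but not all of it: without that library the count was 11138, below the lowest remote count with any mouse left out, 13966, while without mouse 23 in either biopsy the remote count was 1.44 times that of the area at risk, against 1.71 with all mice and 1.89 to 2.15 without any other mouse. Depth does not account for it: with every H3K9me2 library thinned to 416683 counts and every input to 1286383, the remote count was 1.67 times that of the area at risk (1.71 before). A weaker mark across the area at risk stays open, as strength differed by -0.129 on average with an exact sign-flip p of 0.1875 (n = 6), and 4 of 6 mice were lower; without mouse 23 it was -0.0594, and over the mean input of the other mice it then turned to 0.0178 (strength 0.961 in the area at risk and 0.943 in the remote myocardium). The area-at-risk fit also had the larger coefficient of variation, 11.6% against 5.15%, and whether the tissue or the handling of the biopsies set that was not tested. The fit of all 24 libraries at once, also chosen after seeing the data, takes dispersions common to both biopsies. It called 11155 regions in the area at risk and 15523 in the remote myocardium, a smaller gap. Part of the gap thus goes with the separate fits, and part remained.

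The lowest strength of the 12 H3K9me2 libraries, 0.685, was that of the area at risk of mouse 23. Over the mean input of the other mice this library's strength was 0.478, with the next lowest library at 0.765, so the value depends on the input used. A swap with its input library is argued against by that input's own strength of -0.206 against the other inputs, where a swapped label would need a value near that of the mark. Unenriched DNA mixed in would weaken higher and lower regions alike. The kept share of the other mice's change was 0.414 in higher and 0.669 in lower regions. Their difference of -0.255 passes the bound of 0.2 set before. That bound does not single out this library, because mice 22, 27 and 30 differ by -0.240 to -0.283 with the same measure. Mice 17 and 19 stay inside it, at -0.106 and -0.0240. The test therefore does not decide, and this reading was chosen after the values were seen. A fall of strength with library total stays open, since r over the 12 libraries was -0.483 (permutation p = 0.112; rho -0.336, permutation p = 0.289) but 0.0338 without the 2 libraries farthest from the median total, with an interval of -0.609 to 0.65 too wide to decide, a criterion also added after r was seen. Within the biopsies r was -0.672 and -0.205, and no biological explanation was tested for a single library.

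Other splits of the same libraries bear on the counts. For H3K9me2 between biopsies, where 0 regions were called, 24 of 40 splits gave as many as the real 1272 regions at an unadjusted p under 0.05, and the highest other gave 3821, so chance cannot be excluded. In 12 other splits regions were called, up to 167, and the cause was not tested; among the 32 splits that part every mouse's pair, 26 gave as many and the highest other 3042, and 5 called regions, at most 2. For the area at risk against input 1 of 40 splits, the real one, gave as many as 9670 calls, the highest other 3556. For the remote myocardium 1 of 40 gave as many as 16509, the highest other 1. Chance is thus unlikely for both, though 1 in 40 is the smallest share that such a draw can give. Splits that part every pair gave at most 947 and 2219 otherwise. For the inputs 39 of 40 splits gave as many as the real 1157 regions at p under 0.05 (highest other 3907), and for the interaction 29 of 32 gave as many as 1728 (highest other 2658), so chance cannot be excluded there.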

How the results depend on the processing

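The fit of all 24 libraries at once, the fits without the H3K9me2 library of the area at risk of mouse 23, those on regions that overlap no other, all alternatives of the shared regions except FDR 0.01 and a log2 fold change of 0.5, the left-out mice of the interaction, the alternatives of the enrichment strength and the replicate block of the gene lists were chosen after seeing the data. The contrast of H3K9me2 between biopsies kept 0 calls under every other alternative run, and had 1, the Camta2 region, without mouse 19; the range with a mouse left out was 0 to 1. The area at risk against input (9670) gave 5056 at FDR 0.01 and 638 with Bonferroni correction, 6818 to 9698 with a mouse left out, 11138 without the H3K9me2 library of mouse 23, 6917 by DESeq2 and 10994 with the replicate block; the stricter thresholds lower counts by construction. The share of higher regions among its calls was 48.0%, 13.0% under Bonferroni correction and 55.7% among regions at or above the median abundance. The remote myocardium against input (16509) gave 9945 among regions at or above the median abundance, where fewer regions are tested, 2918 with Bonferroni correction, 13966 to 14945 with a mouse left out, 13150 by DESeq2 and 16907 with the replicate block. The inputs stayed at 0 in each alternative, mice left out included (0 to 0), with 1159 regions at an unadjusted p under 0.05 in the replicate block. Without mouse 23 there were 2567 such regions, against 1157 with all mice and 956 to 1365 without any other mouse. The smallest adjusted p by edgeR was then 0.810. The interaction stayed at 0 with the replicate block (1731 regions at an unadjusted p under 0.05), a mouse left out (0 to 0; smallest adjusted p 0.0590, without mouse 19), the mouse 23 library left out, regions that overlap no other and regions at or above the median abundance. Other size factors, no filter, autosomes only and DESeq2 were not run for it. Shared regions (7991) were 4207 at FDR 0.01 and 5565 to 7021 with a mouse left out; matching by any overlap was not applicable, since the regions are identical in all tables.

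Lists past the random-list test between the biopsies were 0, and 1, the odorant receptors, lower in the area at risk, when matched on length too or when a gene was the mean of its regions. In the area at risk against input 3 lists became 9 with the mean over members, 8 with matching on length and 5 with the mean over all regions of a gene. In the remote myocardium 6 became 2 among members at or above the median abundance and 3 with the replicate block. The cause was not tested. For gene bodies the odds ratio of being higher turned from 0.944 to 1.13 with a flank of 5 kb in the area at risk and passed in its own direction at FDR 0.01 (0.890); in the remote myocardium it turned from 1.01 to 0.953 at FDR 0.01 and passed at 1.23 with a flank of 5 kb. The wider flank moves regions near gene ends out of that class. The other position classes kept their direction and side of the threshold. Enrichment strength, area at risk minus remote myocardium (-0.129), ran from -0.171 to -0.0594 with a mouse left out and was -0.118 over the mean input of the other mice. With that input and without mouse 23, which has the largest difference between biopsies, it turned to 0.0178.

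Named regions were chosen by size of change or smallest p, and alternatives that only change a threshold or subset keep the fold changes of the main fit. Much of the agreement below is therefore built in. Of 4809 values of named regions under alternatives 4725 kept their direction and side of the threshold, 75 lost the call, 7 gained it and 2 turned direction. Those were Slc17a7 between the H3K9me2 libraries, at -0.0037 (log2) without mouse 23 (up to 0.46 without mouse 19), and Stra8 between inputs, at 0.0639 (log2) without mouse 23 (down to -0.23 without mouse 27). Neither was called, and the cause was not tested. Of the 7 gained calls 6 are the Mtor region against input in the area at risk, with adjusted p from 0.0205 to 0.0444, and 1 is Camta2. Of 45 list values 35 were the same and 10 lost the call. The replicate block changed no other call of a named region or list than those given beside the results, except fry's for fibroblast markers in the area at risk (adjusted p 0.0461 without it and 0.0928 with it). At these depths, spreads and group sizes 21 of 100 simulated changes of 1.5-fold were called between biopsies (94 tested); whether depth or the spread between mice set this was not tested.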

Other observations

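The balance of enrichment and depletion differed between chromosomes, described here after the values were seen and without a test. Chromosome 13 had the largest share of higher regions among the autosomes, 38.1% of 1086 in the remote myocardium and 22.0% of 1094 in the area at risk, with 9.02% and 4.85% lower. Chromosomes 11 and 19 had the lowest shares of higher regions among them. On chromosome 11, which is rich in genes and holds 10.1% of the listed regions, 13.0% of 3994 were higher and 26.2% lower in the remote myocardium, and 7.72% of 4027 higher and 16.4% lower in the area at risk. On chromosome 19, 14.9% of 1246 were higher and 27.8% lower in the remote myocardium, and 6.55% of 1252 higher and 20.1% lower in the area at risk.

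Sex chromosomes carried values that belong to no contrast. The share of reads on chromosome X was higher in each of the 3 females than in each of the 3 males in every group, for example 0.138% ± 0.0115 against 0.0791% ± 0.00263 in input of the remote myocardium (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest possible). Chromosome Y holds 18 of the listed regions, and most of its reads fall in 2 of them, in the noncoding gene Gm33272 at 90803200 to 90806199 and 90807200 to 90808199. Over a mouse's 4 libraries the longer of them, scaled to CPM, held 12.6, 17.8 and 83.2 in males 27, 23 and 22, and 1.50 and 1.16 in females 17 and 30. Mouse 19, labelled female and with a chromosome X share on the side of the females, held 62.4. Without the genome sequence it was not tested whether these 2 regions lie in sequence shared with chromosome X or that varies between animals, so the value does not tell the sex of the mouse.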
